A study of Mus musculus with 9 samples.

How the data were processed

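Messenger RNA of pancreas from 9 C57BL/6 mice was sequenced, 3 mice in each of 3 groups. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was selected with oligo(dT) beads, and libraries were circularised before sequencing. The strandedness of the libraries and of the counting is not given in the sources used here. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.12 with mouse build GRCm38.p6, without the role of each tool.

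The deposited table lists 17132 genes. Per the file headers, the authors gave read counts, here taken as RSEM's estimated counts, for each gene and library, and 93.5% of these values were whole numbers. FPKM values, scaled by gene length and library total, were also deposited per the file headers. TPM values were deposited by the authors in the same table and were not tested here. Mean columns over libraries of a group were not used. Mitochondrially encoded genes and immunoglobulin constant genes were not analysed here. Gene identifiers of 17031 of the 17132 genes matched the reference annotation of the same build, which gave the coordinates.

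Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with the default expression filter, which left 12828 genes and removed 4304. Libraries were scaled by TMM, and one quasi-likelihood model was fitted to all 9 libraries with group as the only term, leaving 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Levels are given as CPM on the TMM scale, mean ± SD over the 3 mice of a group.

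A set of 34 gene lists, 22 of pathways and 12 of cell types, was fixed before the data were examined. The 32 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Named genes followed a rule fixed at the same time. In each comparison these were the 8 highest and 8 lowest log2 fold changes among passing genes whose groups did not overlap, with a mean of at least 10 CPM in the higher group and no predicted or clone name. Up to 4 members per list with the smallest p and a mean of at least 1 CPM were added, whether or not they passed. With fewer than 10 passing genes, the 8 with the smallest p were named.

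Libraries held 19112923 to 20212744 estimated counts. The common biological coefficient of variation was 0.175, and the median standard error of a log2 fold change lay between 0.19 and 0.21. No pair of replicate libraries agreed within sampling noise. The test was checked on simulated counts with known changes in 200 of the better expressed genes. Genes were drawn independently of each other, with a spread that depended only on expression level. For Model versus Control, 70.7% of 2-fold and 98.7% of 4-fold changes were recovered among 12364 genes. For QYD versus Model the shares were 88% and 100% among 12687 genes, and for QYD versus Control 78% and 99.3% among 12359 genes. A 1.5-fold change was recovered in 26.7%, 30% and 21.3% of cases in the same order. These shares may be too high for the real data, where the spread is particular to each gene and the samples may hold structure. Where few genes truly change, the adjusted threshold is also harder to pass.

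Alternatives tried were RLE scaling, TMM without the 50 most abundant genes, no low-count filter, at least 5 CPM in 3 samples, DESeq2 1.42.0, limma 3.58.1 (voom with sample weights), only the compared groups in the fit, a 2-fold threshold, an adjusted p of 0.1, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with FPKM of at least 1 in 3 samples, and each of the 9 samples left out in turn. Scaling by library size alone and a B cell marker covariate were added after seeing the data. Comparisons that share libraries were set beside 50 simulations without a decoction effect and 50 without any effect.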

Results

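Pancreatic transcripts were measured in 3 groups of 3 C57BL/6 mice. Control mice received saline. Model mice received 7 hourly intraperitoneal injections of caerulein, a cholecystokinin analogue that overstimulates acinar cells, with lipopolysaccharide (LPS) added at the last one. QYD mice received the same injections and Qingyi Decoction, a herbal preparation, at 0 and 8 h. Tissue was taken 24 h after the first injection. Libraries held between 19112923 estimated counts (Model 59) and 20212744 (Control 44). The name of the decoction group is spelled differently in the titles and in the treatment labels, and the titles were used here.

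The libraries differed in composition. Digestive enzyme genes took 81.7% ± 0.53 of counts in Control (SD, n = 3), 47.6% ± 3.07 in Model and 48.9% ± 3.49 in QYD. The 50 most abundant genes took 91.1% ± 0.34, 66.8% ± 2.99 and 69.0% ± 3.18 in the same order. TMM factors averaged 0.381 in Control, 1.70 in Model and 1.56 in QYD. Directions below are therefore relative to the typical gene. On library totals alone the median gene stood 2.15 log2 units higher in Model versus Control than on the TMM scale, and 2.03 higher in QYD versus Control.

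**Figure D1:**
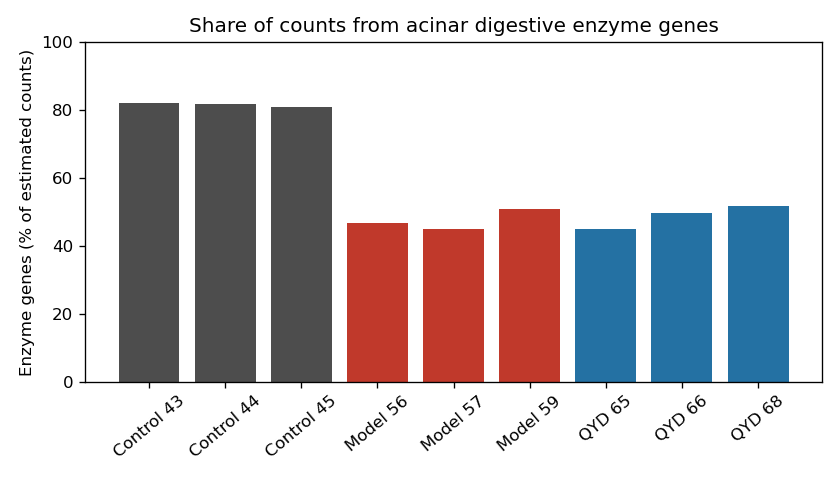
Percentage of estimated counts assigned to acinar digestive enzyme genes in each of the 9 libraries, coloured by group, with 1 bar per mouse. The Control bars lie between 81.1% and 82.0%, and none of the other 6 bars lies above 51.8%.

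The first comparison, Model versus Control, addresses what caerulein with LPS changed in the pancreas. Transcripts of digestive enzymes fell: 31 of 33 tested members were lower and none was higher, with a median log2 fold change of -3.08. Colipase (Clps, chromosome 17, 28558210 to 28560766, GRCm38.p6) went from 42298 ± 6242 to 1682 ± 467 CPM (SD, n = 3), a log2 change of -4.65 ± 0.25 (SE). The cytokine and chemokine list rose, with 22 of 32 members higher, none lower and a median of 2.33, and did not pass with an estimated correlation (adjusted p = 0.25, camera on the edgeR model). Neutrophil markers rose as well, with 16 of 18 members higher and a median of 2.76, and did not pass with an estimated correlation either (0.33). Without Control 45 the medians were 3.33 and 3.71. Lipocalin 2 (Lcn2, chromosome 2, 32384637 to 32387739), an iron-binding acute phase protein, went from 278 ± 404 to 2966 ± 667 CPM. It stood at 37.9, 50.3 and 744 CPM in Control 43, 44 and 45, and its log2 change was 3.42 ± 0.92, against 6.07 ± 0.28 without Control 45.

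In total 5464 of 12828 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2736 higher and 2728 lower. On library size alone 12064 were higher and 121 lower, and 2736 were higher and 121 lower on both scales. The share of higher calls was thus 50.1% or 99.0%.

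Among enzymes, chymotrypsin C (Ctrc) changed by -3.52 ± 0.16 log2 units and the lipase-related Pnliprp2 by -2.82 ± 0.17. The enzyme list stayed lower on library size, with a median of -0.94. Of 28 acinar identity and secretion genes 23 fell and none rose, with a median of -1.50, against 0.63 on library size. Its members Tmed11 (-5.97 ± 0.36), Tmed6 (-3.41 ± 0.19), Erp27 (-2.85 ± 0.15) and the water channel Aqp12 (-2.73 ± 0.16) were lower on both scales. Of 31 genes of the unfolded protein response 21 fell and 2 rose, with a median of -1.01, against 1.15 on library size. Ero1lb, which helps to form disulphide bonds in the endoplasmic reticulum, changed by -3.40 ± 0.21 and Herpud1 by -2.81 ± 0.21 on the main scale. The chaperone Hyou1 changed by -1.50 ± 0.13, against 0.65 on library size. These lists held with an estimated correlation (adjusted p = 0.045 each, camera on the edgeR model with Benjamini-Hochberg adjustment).

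The 8 lowest named genes were Serpini2 (-6.04 ± 0.49; chromosome 3, 75242357 to 75270078), Tmed11, BB114814 (-5.84 ± 0.21), Sostdc1 (-5.81 ± 0.58), Cyp2e1 (-5.65 ± 0.91), Inmt (-4.98 ± 0.54), Clps and Gnmt (-4.57 ± 0.29). The 8 highest were Slfn4 (3.82 ± 0.57; chromosome 11, 83175172 to 83190216), Psrc1 (3.71 ± 0.42), Fut2 (3.67 ± 0.55), Tnfrsf23 (3.58 ± 0.70), the defensin Defb1 (3.56 ± 0.69), the neutrophil-attracting chemokine Cxcl5 (3.55 ± 0.52), Lcn2 (3.42 ± 0.92) and the tight junction gene Cldn4 (3.39 ± 0.67). Without Control 45 Slfn4 stood at 4.62, Psrc1 at 5.25, Fut2 at 5.90, Tnfrsf23 at 4.19, Defb1 at 5.54, Cxcl5 at 5.23 and Lcn2 at 6.07. Without Model 56 Tnfrsf23 stood at 2.99 and Cldn4 at 2.33, without Model 59 Serpini2 at -6.80 and Inmt at -5.74, and without Control 43 Cyp2e1 at -4.73.

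Among cytokine and adhesion genes, Icam1 rose by 2.27 ± 0.27, Ccl2 by 2.77 ± 0.38 and Csf1 by 1.91 ± 0.27. Lif rose by 4.32 ± 0.56, from 0.17 ± 0.07 CPM. Of 32 Toll-like receptor and NF-kB genes 23 rose and 1 fell. Tnip1 (2.10 ± 0.20), Tlr3 (1.94 ± 0.22) and the adaptor Myd88 (1.34 ± 0.16) rose, while Irak1 fell by 1.19 on the log2 scale, with 0.96 on library size. Among neutrophil markers Csf3r (2.75 ± 0.36), Fpr1 (3.22 ± 0.47), Ngp (2.29 ± 0.35) and S100a9 (3.04 ± 0.47) rose. Of 17 inflammasome genes 8 rose and none fell, among them Il1b (3.59 ± 0.56) and Casp4 (1.62 ± 0.33). Of 36 interferon response genes 22 rose and none fell, including Oas1a (2.15 ± 0.29), Isg15 (2.08 ± 0.31) and Irf7 (2.02 ± 0.31). Without Control 45 Csf3r stood at 3.35, Fpr1 at 4.97, S100a9 at 4.10, Il1b at 5.18 and Isg15 at 2.71. With an estimated correlation the adjusted p was 0.25 for cytokines, 0.13 for Toll-like receptor genes, 0.33 for both neutrophil and inflammasome genes and 0.52 for interferon genes (edgeR model, camera).

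Duct and metaplasia genes rose in 18 of 29 cases and fell in 3. The epithelial adhesion gene Epcam (1.98 ± 0.19), clusterin (Clu, 2.32 ± 0.33) and Cd44 (2.38 ± 0.37) rose, and Tff2 fell (-3.62 ± 0.18). Without Control 45 Clu stood at 2.91 and Cd44 at 3.04. Acute phase and stress genes rose in 17 of 29 cases and fell in 5. Ceruloplasmin (Cp) rose by 1.96 ± 0.26, while Itih4 (-2.39 ± 0.27), the trypsin inhibitor Spink1 (-1.62 ± 0.20) and Reg3d (-1.94 ± 0.27) fell. On library size Spink1 stood at 0.52, and Reg3d (0.19) and Itih4 did not pass. Cell death genes rose in 20 of 30 cases and fell in 1, with Bak1 (2.01 ± 0.17), Bax (2.06 ± 0.25) and Tnfrsf1a (1.06 ± 0.11) higher. Casp9 was lower (-2.54 ± 0.27) and did not pass on library size. Extracellular matrix genes rose in 17 of 30 cases and fell in 3, with Mmp3 (2.26 ± 0.23) and Tgfb1 (1.02 ± 0.15) higher. Cholesterol genes rose in 14 of 21 cases and fell in 1, with Hmgcs1 at 1.40 ± 0.22. Immediate early genes rose in 10 of 21 cases and fell in 2, with Junb at 2.05 ± 0.23. Cell cycle genes rose in 7 of 33 cases and none fell, with Mcm6 at 1.73 ± 0.18 and Mcm4 at 1.93 ± 0.24. With an estimated correlation none of these 7 lists passed, with adjusted p from 0.23 to 0.67 in the edgeR model.

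All 61 cytosolic ribosomal protein genes fell, with a median of -0.996, and 44 of 46 respiratory chain genes fell, with a median of -0.81. On library size the medians were 1.16 and 1.34. Rps25 changed by -1.37 ± 0.15 and Rpl3 by -1.20 ± 0.14, against 0.78 and 0.95 on library size. Ndufa1 changed by -2.02 ± 0.15, against 0.12, which did not pass. Of 17 islet markers 12 fell and 1 rose, with a median of -1.56, against 0.63 on library size. Insulin (Ins2) changed by -2.25 ± 0.31 and somatostatin (Sst) by -2.71 ± 0.25, and neither passed on library size. Chromogranin A (Chga) changed by -1.76 ± 0.27, against 0.40, which did not pass either. All 5 tested red blood cell markers fell, with a median of -1.94, against 0.21 on library size and -1.28 without Control 43. With an estimated correlation the adjusted p was 0.33 for ribosomal and islet genes, 0.25 for the respiratory chain and 0.54 for red blood cell markers in the edgeR model.

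The remaining tested lists did not pass camera. Heat shock genes rose in 7 of 17 cases and fell in 1, with Hspb1 at 1.99 ± 0.21. Oxidative stress genes rose in 14 and fell in 7 of 32 cases, with Pgd at 1.25 ± 0.14 and Prdx4 and Gstm1 at -2.77 ± 0.17 and -3.16 ± 0.20. Autophagy and lysosome genes rose in 10 and fell in 3 of 28 cases, with cathepsin B (Ctsb) at 0.85 ± 0.13. Xenobiotic response genes rose in 7 and fell in 6 of 16 cases, with Abcc3 at 2.07 ± 0.28 and Gstm2 at -3.64 ± 0.18. Macrophage markers rose in 8 and fell in 2 of 22 cases, with Msr1 at 2.15 ± 0.35 and Chil3 at 2.73 ± 0.52, against 3.84 without Control 45. Circadian genes rose in 1 and fell in 6 of 19 cases, and glucocorticoid and fasting genes rose in 4 and fell in 5 of 18. Adipocyte markers fell in 5 of 13 cases and rose in 1, stellate and fibroblast markers fell in 5 of 14 and rose in 1, endothelial markers rose and fell in 3 of 15 each, and mesothelial markers fell in 2 of 8. On library size the medians were 1.52 for circadian, 2.00 for glucocorticoid, 0.27 for adipocyte, 1.58 for fibroblast, 2.23 for endothelial and 1.22 for mesothelial genes. Of these lists only the adipocyte markers had members that passed as lower there, 2 of 13. Intestinal epithelium markers, with 3 tested members, rose in 2 cases. No B cell or T cell marker passed, and no mitochondrially encoded gene was analysed here.

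Of the lists, 19 of 32 passed camera with the preset correlation, 12 upward and 7 downward, and 3 with an estimated one. Adjusted over the list alone, 32 of 33 enzyme genes, 23 of 32 cytokine genes, 16 of 18 neutrophil markers and 21 of 29 acute phase genes were called in the direction of their list. The cell cycle list was lost without Control 44 or Model 57, and the red blood cell list without Control 43, Model 56 or Model 57. Heat shock, adipocyte, fibroblast, macrophage, circadian and B cell lists passed only with a library left out. Heat shock genes did so without Control 45, Model 57 or Model 59, adipocyte markers without Control 45, Model 57 or QYD 68, fibroblast markers without Control 45, Model 56 or Model 57, macrophage markers without Control 45 or Model 59, circadian genes without Control 45 and B cell markers without Model 57. In 74 genes above 50 CPM in Model and above 20 times the mean of Control 43 and 44, on library totals, Control 45 lay at a median of 5.34% of the way from that mean to the mean of the 6 injured libraries. Without Control 45 5117 genes passed.

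**Figure D2:**
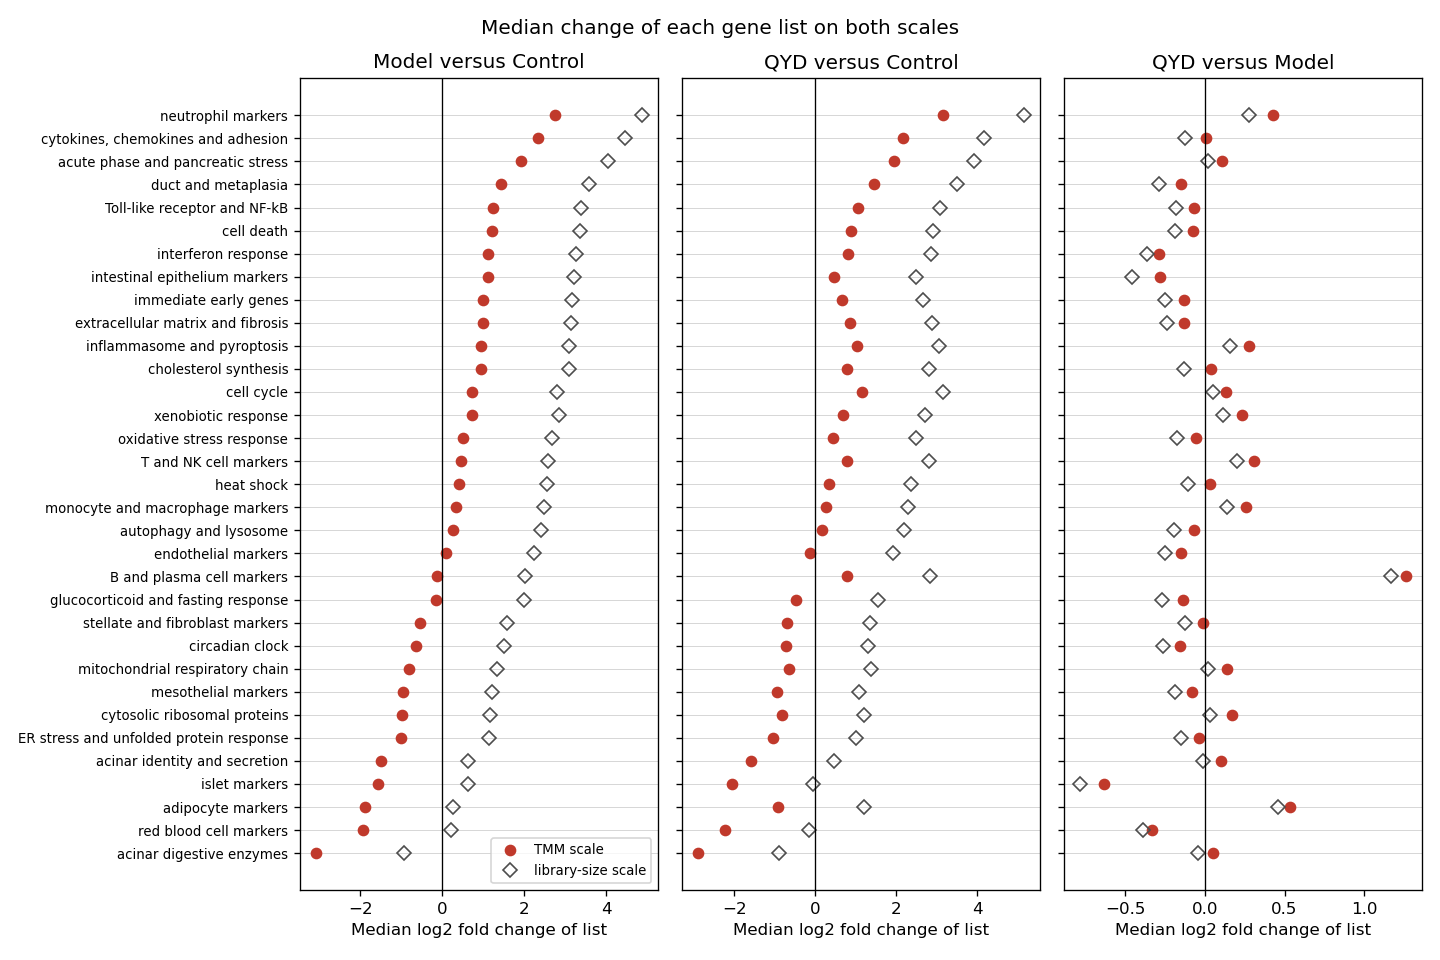
Median log2 fold change of the tested members of each gene list in the 3 comparisons, on the TMM scale (filled circles) and on library size (open diamonds). On library size ribosomal genes lie at 1.16 in Model versus Control, against -0.996 on the TMM scale.

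QYD versus Model addresses the effect of the decoction in injured mice. Clps stood at 1746 ± 195 CPM in QYD and 1682 ± 467 in Model (SD, n = 3), a log2 fold change of 0.05 ± 0.21 (SE). The kallikrein Klk1b4 (chromosome 7, 44207433 to 44211754) stood at 17.8 ± 4.19 CPM in QYD and 8.69 ± 2.12 in Model, a log2 fold change of 1.04 ± 0.21. Neither passed the test. No gene passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in which the smallest adjusted p was 0.83. At an unadjusted p under 0.05 there were 750 of 12828 genes, against 641 expected by chance. Simulations with no decoction effect, with genes drawn independently, gave 602 ± 25 (SD). On library size there were 505 genes. There were 353, 557, 568 and 559 without QYD 66, Model 56, Model 59 and QYD 68. Without Control 43, Control 44, Control 45, Model 57 and QYD 65 there were 986, 1061, 811, 843 and 796. With only the compared groups in the fit there were 1277 of 12759. DESeq2 called 0 genes (714 of 17100 unadjusted), limma-voom with sample weights 1 (1530 of 12828) and limma on log2(FPKM + 1) and log2(FPKM + 0.1) 1 each (698 and 390 of 10382), which was Hist2h2aa2 in each case. That histone gene was at 0.37 ± 0.04 CPM in Model and listed at 0 in every QYD and Control library, and 0% of its 50-base stretches are unique to it, so its counts are uncertain.

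The other genes with the smallest p did not pass either. Cd300lg (1.15 ± 0.24), the histamine-degrading Hnmt (0.82 ± 0.17) and Serpini1 (0.78 ± 0.17) had positive values. Hap1 (-1.05 ± 0.21), Inhbb (-0.88 ± 0.18) and the interferon-induced Xaf1 (-0.76 ± 0.16) had negative ones. The enzyme list had a median of 0.05, against -0.04 on library size. Its members Amy1 and Try5 did not pass, and Amy1 stood at 0.76 ± 0.17 and Try5 at 0.67 ± 0.26. The cytokine list had a median near 0, and -0.12 on library size, with Csf3 at -1.10 ± 0.32, Ptgs2 at -1.19 ± 0.51 (-1.93 without QYD 68) and Il1b at 0.67 ± 0.33.

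Of the 32 lists 9 passed camera with the preset correlation and none with an estimated one, where the smallest adjusted p was 0.80 in the edgeR model. Of members adjusted over the list alone, 1 each was called in the enzyme, interferon, islet and glucocorticoid lists, and none over all genes. Upward lists were the respiratory chain (median 0.14, Cox7b 0.51 ± 0.14, Ndufa5 0.38 ± 0.12), ribosomal proteins (0.17, Rpl22 0.37 ± 0.17), B and plasma cell markers (1.26, and 4.16 without Model 57) and neutrophil markers (0.43, Mmp8 0.78 ± 0.35). Downward lists were islet markers (-0.63, G6pc2 -1.23 ± 0.32, Ttr -0.65 ± 0.20, Chga -0.81 ± 0.27), interferon response (-0.29, Oasl1 -0.68 ± 0.19, Usp18 and Isg15 -0.73 ± 0.24 each), glucocorticoid and fasting genes (-0.14, Ddit4 -0.70 ± 0.18, Pdk4 -0.39 ± 0.15), endothelial markers (-0.15, Kdr -0.37 ± 0.18) and extracellular matrix (-0.13, but 0.034 without Model 57 and -0.30 without QYD 65). On library size the medians were 0.019 for the respiratory chain, 0.031 for ribosomal proteins, 1.17 for B cell, 0.28 for neutrophil, -0.78 for islet, -0.37 for interferon, -0.27 for glucocorticoid, -0.25 for endothelial and -0.24 for matrix genes. B cell markers differed between libraries of one group, with Cd79a at 97 counts in Model 57 and 2 in Model 59, and 182 in QYD 66 and 9 in QYD 68. Without QYD 68 the interferon, ribosomal, neutrophil, endothelial and matrix lists no longer passed, without QYD 66 the B cell, endothelial and matrix lists did not, and without Model 57 16 lists passed in place of 9. Other lists passed only with a library left out. Duct and immediate early genes did so without Model 57, Model 59 or QYD 68, cell cycle, adipocyte and cholesterol genes without Model 57 or QYD 68, macrophage markers without Control 45, Model 57 or QYD 68, T cell markers without Control 43, Control 44, Control 45, Model 57 or QYD 68, inflammasome genes without Control 44, Control 45 or Model 57, red blood cell markers without Model 57 or QYD 65, enzymes without Model 59 or QYD 65, and acinar identity genes without Model 59. The glucocorticoid list was lost without Model 59 or QYD 65, the neutrophil list without Model 59, the endothelial and matrix lists without Model 57, and the matrix list without Model 56.

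**Figure D3:**
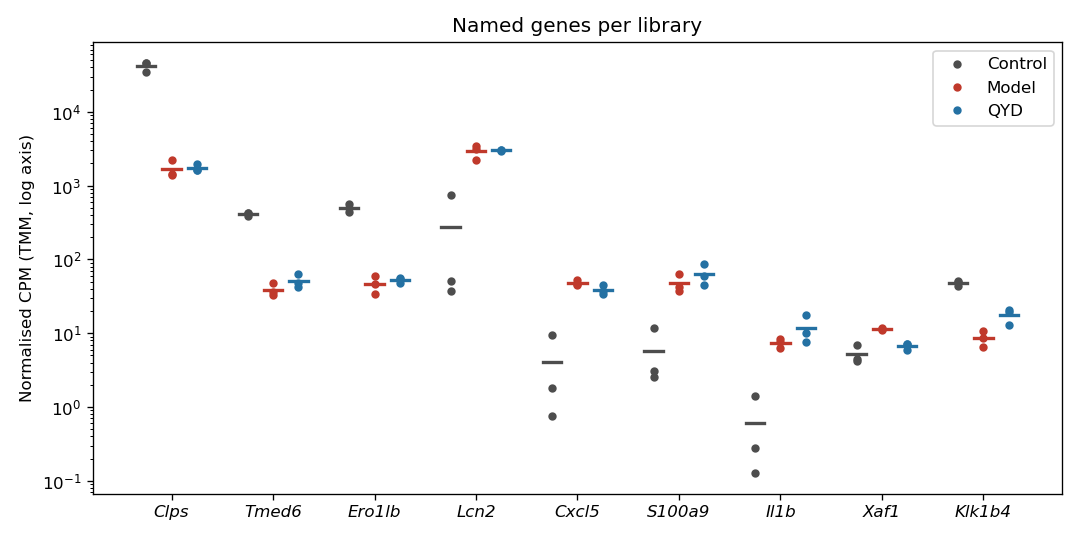
Normalised CPM (log axis) of 9 named genes in the 9 libraries, 1 point per mouse and a line at each group mean. Clps lies at 1682 in Model and 1746 in QYD, against 42298 in Control.

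**Figure D4:**
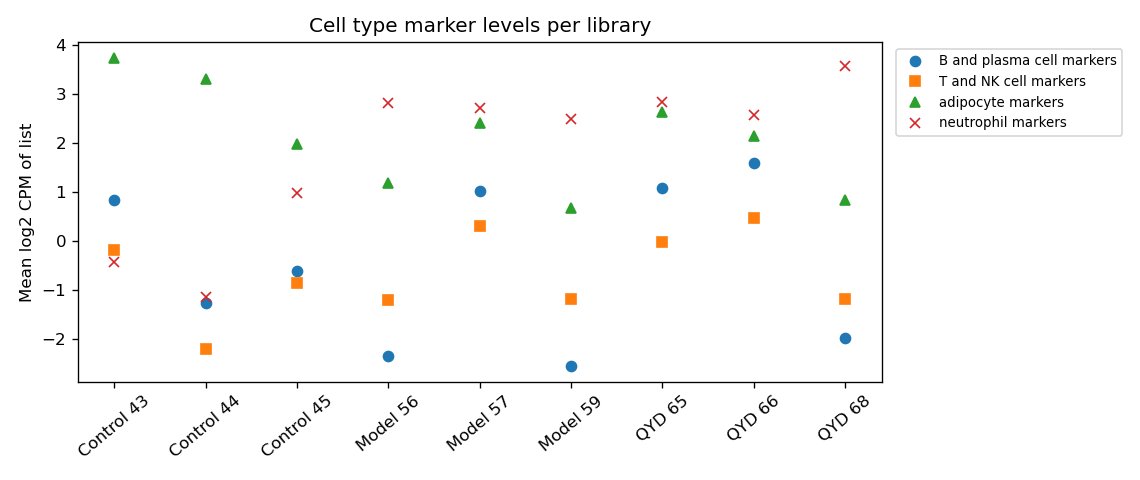
Mean log2 CPM of 4 cell type marker lists in each of the 9 libraries, with 1 symbol per list. B and plasma cell markers lie at 1.58 in QYD 66 and -1.97 in QYD 68.

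Reversal of the Model changes by the decoction was examined in the same fit. No gene was called in Model versus Control and called with the opposite sign in QYD versus Model. Among the 5464 genes called in the former, 64.3% had the opposite sign in the latter, against 56.7% ± 0.62 (SD) in 50 simulations with no decoction effect, since both comparisons use the Model libraries. That SD holds for genes drawn independently and does not measure the spread between mice. The covariance of the fold changes over all genes was -0.0654, against -0.0376 ± 0.0037 without a decoction effect and -0.0393 ± 0.0017 with no effect at all, where genes were drawn independently of each other. Of the 20 labelled splits of the 6 injured libraries, 7 gave a covariance at least as negative, so labels other than the real ones gave it too. Over the same splits the share of opposite signs ran from 36.4% to 72.8%. The highest share came with Model 56, Model 57 and QYD 66 labelled as Model, so a share above 64.3% did not need the real labels.

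The third comparison, QYD versus Control, addresses what remained different from saline mice under the decoction. Enzyme genes were again lower, with 31 of 33 members lower, none higher and a median of -2.89. Neutrophil markers were higher in 16 of 18 cases with a median of 3.17, and cytokine genes in 23 of 32 with a median of 2.17. With an estimated correlation neither list passed (adjusted p = 0.25 each), and nor did the enzyme list (0.077). Without Control 45 the medians of neutrophil and cytokine genes were 4.24 and 3.20. Interleukin 1 beta (Il1b, chromosome 2, 129364569 to 129371164) went from 0.60 ± 0.69 CPM in Control to 11.8 ± 5.42 in QYD, a log2 change of 4.26 ± 0.55, against 5.85 without Control 45.

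By edgeR's quasi-likelihood test 5222 genes passed, 2624 higher and 2598 lower; on library size 12028 were higher and 127 lower. The other highest genes were Slfn4 (3.83 ± 0.57), the neutrophil collagenase Mmp8 (3.78 ± 0.50), Retnlg (3.72 ± 0.55), Hoga1 (3.66 ± 0.48), Fpr1 (3.54 ± 0.47), Chil1 (3.54 ± 0.65) and Chil3 (3.51 ± 0.52). Without Control 45 Slfn4 stood at 4.63, Mmp8 at 5.20, Retnlg at 5.10, Hoga1 at 4.37, Fpr1 at 5.30 and Chil3 at 4.61. Chil1 was at 0 CPM in Control 43 and 44 and stood at 2.95 without Control 44 and 11.02 without Control 45. The lowest were BB114814 (-6.41 ± 0.22), Serpini2 (-5.72 ± 0.48), Sostdc1 (-5.33 ± 0.56), Tmed11 (-5.19 ± 0.34), Inmt (-5.11 ± 0.55), Cyp2e1 (-5.10 ± 0.87), Clps (-4.60 ± 0.25) and Ppp1r1b (-4.53 ± 0.34). Without Control 43 Cyp2e1 stood at -4.19.

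Of 32 lists 22 passed camera, and none with an estimated correlation, where the smallest adjusted p was 0.077 in the edgeR model. Upward lists were duct, acute phase, cytokine, Toll-like receptor, inflammasome, interferon, cell cycle, matrix, cell death, immediate early, cholesterol, neutrophil and macrophage genes. Downward lists were enzyme, acinar identity, unfolded protein response, respiratory chain, ribosomal, circadian, islet, fibroblast and red blood cell genes. On library size the medians of acinar identity (0.47), unfolded protein response (1.00), respiratory chain (1.39), ribosomal (1.21), circadian (1.30) and fibroblast (1.36) genes were positive. Adjusted over the list alone, 31 of 33 enzyme, 25 of 32 cytokine and 17 of 18 neutrophil genes were called. The immediate early and macrophage lists were lost without Control 44, the former also without Control 45 and the latter without QYD 66. The fibroblast list was lost without Control 43, Control 44, Model 59, QYD 66 or QYD 68, and the circadian list without Control 43, Model 56, Model 59 or QYD 66. Heat shock genes passed only without Control 43, Control 45 or QYD 65, and adipocyte markers only without QYD 65. Without Control 45 4932 genes passed.

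Genes called in both Model versus Control and QYD versus Control numbered 2234 higher and 2306 lower in both, with 0 in opposite directions. Independent lists would share 560 and 552. Simulations with no effect gave 0 of each, but called only 0.22 genes on average in Model versus Control and 0.1 in QYD versus Control. That 0 was thus nearly fixed beforehand and does not measure what the shared Control libraries add. In 50 simulations with no decoction effect the shared genes numbered 2351 and 2387 on average and at least 2287 and 2323, so both observed numbers lay below the simulated range. The covariance of both fold changes was 1.03, against 0.0726 ± 0.0032 with no effect, and lay 0.163 below the mean of the simulations with no decoction effect (SD 0.0172), where the lowest was 1.16. Those counts were drawn around fitted means, which already hold sampling noise, and genes were drawn independently of each other. Observed values below the simulated range therefore do not by themselves point to a decoction effect. Part of the overlap may come from the shared Control libraries, which were too few to divide.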

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

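Scaling by library size, the B cell marker covariate and, for the reversal, limma, the compared groups alone and an adjusted p of 0.1 were chosen after seeing the data. The number of changed genes in Model versus Control was 2642 at 2-fold or more, 10083 and 10086 with limma on log2(FPKM + 1) and log2(FPKM + 0.1) and 12185 on library size. In QYD versus Control it was 2463, 10077, 10071 and 12155 in the same order. The library-size counts follow from leaving out the composition scaling. FPKM values are scaled by library total as well, and 99.0% of calls in Model versus Control were higher with either FPKM setting and on library size. No separate test of the FPKM counts was made. With the other settings it stayed within 1.5 times, and with 1 library left out it ranged from 4583 to 5307 and from 4237 to 5139. QYD versus Model kept 0 genes, except for 1 with limma-voom with sample weights and with limma on log2(FPKM + 1) and log2(FPKM + 0.1), which was also the 1 gene called with opposite signs.

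With an estimated correlation 3, 0 and 0 lists passed in Model versus Control, QYD versus Model and QYD versus Control. With 1 library left out 18 to 24, 6 to 16 and 19 to 24 passed. For the reversal of Model changes in QYD, the share of opposite signs was 65.1% without the low-count filter, 66.7% with limma-voom and 64.97% with the compared groups alone. It was 65.6% at 2-fold, 63.1% at an adjusted p of 0.1 and 61.9% to 72.7% with 1 library left out, and the cause was not tested. On log2(FPKM + 1), log2(FPKM + 0.1) and library size it was 71.0%, 70.9% and 70.3%. There 99.0% of Model versus Control calls were higher, and the median QYD versus Model change was -0.090, -0.112 and -0.112. Such a shift raises the share without a reversal of single genes, so these shares cannot be set beside the others.

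Signs turned on log2(FPKM + 1), log2(FPKM + 0.1) and library size, values in that order. In Model versus Control list medians became 1.17, 1.17 and 1.16 for ribosomal proteins, 1.29, 1.34 and 1.34 for the respiratory chain, 0.64, 0.73 and 0.63 for acinar identity, 1.11, 1.13 and 1.15 for the unfolded protein response, 0.43, 0.55 and 0.63 for islet markers and 0.40, 0.41 and 0.21 for red blood cell markers. In QYD versus Control they became 1.22, 1.22 and 1.21 for ribosomal proteins, 0.47, 0.56 and 0.47 for acinar identity, 0.81, 0.99 and 1.00 for the unfolded protein response, 1.36, 1.41 and 1.39 for the respiratory chain, 1.18, 1.57 and 1.36 for fibroblast markers and 0.92, 1.39 and 1.30 for circadian genes. In Model versus Control Hyou1 was at 0.61, 0.65 and 0.65, Irak1 at 0.90, 0.96 and 0.96, Spink1 at 0.52, 0.52 and 0.52, Reg3d at 0.16, 0.16 and 0.19, Rps25 at 0.77, 0.78 and 0.78, Rpl3 at 0.94, 0.94 and 0.95, Ndufa1 at 0.12, 0.12 and 0.12, and Chga at 0.33, 0.37 and 0.40. The median of extracellular matrix and fibrosis, QYD versus Model, ranged from -0.30 without QYD 65 to 0.034 without Model 57. Of the values of named genes under other settings, 24 turned in Model versus Control, of which the 9 of Reg3d, Ndufa1 and Chga did not pass, 10 others kept their direction and lost their call, and 1440 kept both. In QYD versus Model 3 gained a call, each of them Hist2h2aa2, and 551 did not. In QYD versus Control all 316 kept direction and call, but these cover only the 16 highest and lowest genes named above and no other list members. With 3 mice per group, 30% of simulated 1.5-fold changes were recovered in QYD versus Model, a share that may be too high for the real data.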

Other observations

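The tests of Control 45 and of the 50-base stretches unique to each gene were set before their results were seen. The tests against single injured libraries, with genes chosen on 1 control, on stretches outside the pair and of the spread of the class ratio of Control 45 were chosen after the result was seen. Among trypsinogen genes, which were chosen here after their values were seen, directions differed. Try4 (log2 -3.09 ± 0.30), Prss2 (-2.44 ± 0.23) and 2210010C04Rik (-3.37 ± 0.27) were lower in Model versus Control, while Gm2663 (2.98 ± 0.70; chromosome 6, 40995822 to 40999479) and 1810009J06Rik (2.62 ± 0.63; chromosome 6, 40964772 to 40968427) were higher. Try5 and Try10 were lower too, without passing on library size, and Prss1, Prss3, Gm5771 and Gm10334 passed on library size, where they were higher, and not on the main scale. There Prss3 passed as lower without Model 59 (-1.46), and Prss1 (1.27) and Gm10334 (1.45) passed as higher without Model 56. On library size Gm2663 stood at 5.10 and 2210010C04Rik at -1.23. Gm2663 reached 6403 ± 819 CPM in Model and 10579 ± 3367 in QYD, against 812 ± 936 in Control, with 388, 164 and 1885 in Control 43, 44 and 45. Without Control 45 its log2 change was 4.54 and that of 1810009J06Rik 3.74, and without any other library both were still higher.

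Reads shared between Gm2663 and 1810009J06Rik may set the values of each, since only 16.5% of the 50-base stretches of Gm2663 are found in no other gene of the reference. Of 100-base stretches 30.7% were unique to Gm2663 and 32.4% to 1810009J06Rik, so the extent of sharing depends on the length taken. Reads shared with the relatives that fell are argued against for exact matches, because 100% of the 50-base stretches of both transcripts occur in no gene outside the pair. Reads placed with mismatches were not examined. Relatives that fell would also bring fewer reads in Model, so this test was not needed to explain a rise. Sharing within the pair only moves counts between its members, so it does not account for both being higher. On library size Gm2663 stood at 5.10 and 1810009J06Rik at 4.72. A rise in the counts of the pair as a set was thus measured, and its cause was not tested. How the rise divides between the members cannot be read from these counts.

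Control 45 lay toward the injured libraries. Over 74 genes above 50 CPM in Model and above 20 times the mean of Control 43 and 44, its level was 5.34% of the way to the injured mean (10th to 90th percentile 3.18% to 7.68%). With genes chosen in the same way on Control 43 alone, Control 44 lay at 0.20% and Control 45 at 5.49%, and with genes chosen on Control 44 alone, Control 43 lay at 0.55% and Control 45 at 5.59%, so being left out of the choice does not account for the level of Control 45. A candidate explanation is an admixture of reads or RNA of an injured library, which would give 1 fraction for every gene class against that library. Class medians differed 3.69 times against the mean of the 6 injured libraries (2.5th percentile over 2000 draws of genes 2.22), and 2.28 times (1.72) without the immediate early genes, in which Control 43 and 44 differ by 3.21%. The highest class in both was the interferon genes (7.14%), in which Control 43 and 44 also differ. Against Model 57 that difference had a median of 2.31%, beside 4.79% for Control 45. Both ratios (3.69 and 2.28) passed the bound of 2 that had been set beforehand against an admixture, but the 2.5th percentile of the second lay under it. The ratio that noise alone gives with 1 true fraction was not computed, so passing the bound does not decide. That bound was set on the mean of 6, which is not what 1 library would bring, and single libraries gave other ratios. Against Model 56 and QYD 68 they were 6.17 (4.14) and 7.80 (4.61), and 4.24 (2.82) and 5.88 (3.87) without the immediate early genes, which argues against either as the source. For QYD 68 the ratios rest on the interferon genes as the highest class (17.5%). Against Model 57, the library with the narrowest spread, the ratio was 2.86 (1.62). It was 1.68 (1.41) without the immediate early genes, a class set aside only after its value was seen. Model 59, QYD 65 and QYD 66 gave 3.98 (2.36), 3.52 (1.88) and 3.13 (1.87), and 2.55 (1.93), 1.95 (1.70) and 1.81 (1.58) without it. The draws reached under 2 for Model 57, QYD 65 and QYD 66, and for Model 59 without that class, so an admixture from 1 of these and a mild response of mouse 45 itself, for which 3.69 is also the value, cannot be told apart.

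B cell and adipocyte markers varied within groups. Cd79a counted 28, 11 and 13 in Control 43, 44 and 45, then 5, 97 and 2 in Model 56, 57 and 59, and 108, 182 and 9 in QYD 65, 66 and 68. The adipocyte gene Cfd counted 628, 347 and 73 in the Control libraries, 151, 957 and 53 in the Model libraries and 1418, 640 and 110 in the QYD libraries, in the same order. Among the injured libraries both genes counted lower in Model 56, Model 59 and QYD 68 than in Model 57, QYD 65 and QYD 66, a division that cuts across the groups. The values fall into separate clusters with fewer than 6 libraries each, so their relation was not tested.

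Other splits of the 6 libraries of a comparison were fitted with both groups alone. For Model versus Control the real split gave 4810 genes and the highest other 0; 1 of 10 splits was as large. For QYD versus Control the values were 4860 and 0, with 1 of 10. For QYD versus Model the real split gave 0 genes, so all 10 splits had to give as many and this count says nothing about chance. The split of Model 56, Model 59 and QYD 68 from Model 57, QYD 65 and QYD 66 gave 182, which points to a structure of the samples. It is also the division of the injured libraries by Cd79a and Cfd counts, and its cause was not tested. With 10 splits no share can fall under 0.05. The covariance behind the reversal was -0.0654 in the real labelling and reached -0.114 in another, with 7 of 20 at least as negative, and 20 splits cannot give a share under 0.05 either.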
